A study of Mus musculus with 6 samples.

How the data were processed

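Hearts of C57 mice were measured by single-cell RNA sequencing with the 10x Genomics Chromium 3' kit (version 3.1, per the submitters' protocol notes), in 3 groups of 2 libraries: control, CLP 12h and CLP 24h. How the control mice were handled, the sex and age of the mice and the preparation of the cells are not given in the sources used here. The values analysed were the deposited raw UMI counts per gene and cell barcode, 1 matrix per library, made with Cell Ranger 5.0.1 per the file headers, with genome build mm10 per the submitters' processing notes. Those notes also name Seurat 3.1.4 without a role; no normalized values were used. The matrices hold whole numbers, 31253 genes, and no barcode below 500 UMIs. Positions of genes were taken from the GENCODE annotation of mm10 by gene ID.

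Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the cells with the highest scores were removed up to the expected share of 0.8% per 1000 cells, since the automatic threshold marked few cells. The kept cells of all libraries were scaled to 10000 counts, log-transformed and reduced to 2000 variable genes, 40 principal components and 20 neighbours, and clustered by Leiden at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Python 3.11.15). No integration across libraries was applied. A cluster was named after a cell class when at least 3 of its markers were detected in at least 10% of its cells and stood at least 2-fold over the lower quartile of clusters. It was left unnamed when proliferation genes led it, when its leading 10 genes held more markers of another class, or when its median UMIs lay under 0.333 of the sample's with no marker among those 10 genes. Class names carry the ending "-like" because they rest on RNA alone. The 95% confidence intervals of class shares are exact binomial (Clopper-Pearson).

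Raw UMI counts were summed per library and class, so that the library and not the cell was the unit of the tests. A class was tested if every library held at least 50 of its cells, which 5 classes met: endothelial, fibroblast, macrophage or monocyte, mural and erythroid-like. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in a fit to all 6 libraries with group as the only term and 3 residual degrees of freedom, in R 4.3.3. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg over genes. The class sums of endothelial-like cells held 22292450 to 33227141 UMIs, those of fibroblast-like cells 4807048 to 8489561 and those of macrophage or monocyte-like cells 2084408 to 3709224. The common biological coefficient of variation was 0.171, 0.137 and 0.204 in the same order. The cells per class were tested with edgeR against the kept cells of each library, with adjustment over classes.

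The 25 gene lists, chosen before the data were examined together with the tests and the alternatives, were tested with camera (limma 3.58.1) on voom values with the correlation between genes set to 0.01 and adjusted over lists; a list needed 3 tested members. Counts of called members are given over all genes and again adjusted over the list alone. Genes to name in the text were also fixed by a rule before the data were examined. For each class and comparison with control, the rule named the 6 largest rises and 6 largest falls among called genes with an absolute log2 fold change of at least 1, a mean of at least 50 CPM in the higher group and both libraries of one group above both of the other. Gm, Rik, mitochondrial, ribosomal and haemoglobin genes were left out there. It further named up to 4 members of each list with the smallest adjusted p, and the markers. For CLP 24h against CLP 12h it named 4 rises and 4 falls. A fold against a group without a UMI was computed against a floor of 3 UMIs over the group. Differences between classes in the response to CLP were tested as an interaction in edgeR across 2 classes, with each library entering as a pair of sums.

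The procedure was tested on simulated data with the depth and the common coefficient of variation of each of the 3 main classes. In each simulation of genes, 200 genes changed, raised and lowered in near-equal numbers. Every gene of a class had the same spread, and no shift of most genes was simulated. The rates below therefore do not cover genes with a wider spread or the dependence on scaling. In the 3 main classes edgeR recovered 87.9% to 95.5% of 4-fold and 22.4% to 64.2% of 2-fold changes, with 0 to 6 unchanged genes called. camera found a raised list in 9 of 9 simulations and called 0 others. The genes of these lists were drawn independently, so false calls among genes that move together were not tested. The test of class differences recovered 69.7% of 4-fold and 7.46% of 2-fold differences.

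The alternatives were DESeq2-type size factors, the DESeq2 1.42.0 Wald test, no low-count filter, the replicate number as a block, a fit to only the 2 groups compared, and each library left out. Further ones were a stricter cell filter (500 genes, 10% mitochondrial), doublets kept, classes by the highest marker score, no genes under 0.1 of their level in another class, and sums thinned to equal totals. For lists they were camera with an estimated correlation and fry, and for shares DESeq2, TMM over classes and shares of cells other than neutrophil-like. Scaling by library size without normalization factors was added after the data were seen. Figures were drawn with matplotlib 3.10.9. Barcodes over the mitochondrial maximum were left out of the comparisons, and classes with fewer cells were given as values only.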

Results

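Single-cell RNA was sequenced from the hearts of C57 mice, either controls or mice 12 or 24 hours after cecal ligation and perforation (CLP). CLP is a surgical model of sepsis in which the cecum is tied off and punctured so that gut bacteria reach the abdominal cavity. The series title places the groups at different degrees of septic shock, so the comparisons ask how the cells of the heart differed from control at each time, and how the later time differed from the earlier one. Each of the 3 groups (control, CLP 12h and CLP 24h) had 2 libraries, which the design text counts as mice. The deposited counts held 54065825 and 50841902 UMIs in the control libraries, in 9127 and 8608 barcodes. The CLP 12h libraries held 57345877 and 49167718 UMIs in 12115 and 10133 barcodes, and the CLP 24h libraries held 59419199 and 61383455 UMIs in 9934 and 15899 barcodes. After the cell filter and the removal of predicted doublets, 7391 and 6252 control cells, 5782 and 6228 CLP 12h cells, and 6632 and 6321 CLP 24h cells remained. Their median depth lay between 5050.0 UMIs (control replicate 1) and 6602 UMIs (CLP 12h replicate 1). Unless another unit is given, gene levels are CPM (UMIs relative to the library's total for the class, scaled by the trimmed mean of M-values, TMM), as mean ± SD over n = 2 libraries. The p-values measure the spread between libraries, and 2 libraries per group give that spread few degrees of freedom.

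The CLP libraries held more barcodes with a high mitochondrial share than the controls. Barcodes that passed the other minimums but had over 20% mitochondrial UMIs made up 12.5% and 22.1% of the control barcodes, 40.1% and 31.4% of the CLP 12h barcodes, and 25.9% and 44.4% of the CLP 24h barcodes. These barcodes were left out of every comparison of cells and genes.

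**Figure D1:**
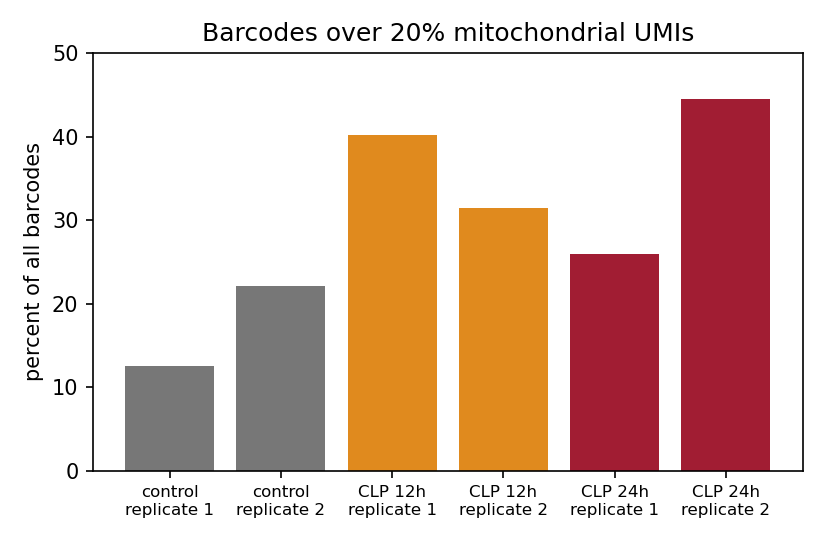
Barcodes with over 20% mitochondrial UMIs as a percent of all barcodes (y axis), 1 bar per library. The 4 CLP libraries lie between 25.9% and 44.4%, and the control libraries at 12.5% and 22.1%.

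Endothelial-like cells were the most abundant class in every group, with 53.1% ± 0.957 (SD, n = 2) of kept cells in control, 58.4% ± 0.946 at CLP 12h and 66.1% ± 2.61 at CLP 24h. When each kept barcode was placed by its highest marker score alone, doublets included, the endothelial share was 70.8% ± 1.80, 65.8% ± 0.438 and 74.2% ± 2.78, so the step from control to CLP 12h was then a fall. Fibroblast-like cells made up 10.3% ± 0.582, 14.1% ± 0.969 and 7.77% ± 1.95 in the same order, and macrophage or monocyte-like cells 5.08% ± 0.797, 5.90% ± 1.33 and 4.47% ± 1.60. Neutrophil-like cells, the first white cells that enter inflamed tissue, averaged 0.424% ± 0.237 in control, 2.25% ± 1.57 at CLP 12h and 0.885% ± 0.603 at CLP 24h. T-like cells averaged 0.234% ± 0.0139, 0.819% ± 0.432 and 2.12% ± 1.88, and mesothelial-like cells, which line the heart's outer surface, 0.0271% ± 0.0383, 1.03% ± 0.888 and 0.207% ± 0.0694. Clusters left unnamed held 20.2% ± 0.962 of control cells, 5.12% ± 1.30 of CLP 12h cells and 5.03% ± 5.5 of CLP 24h cells. The largest of them, clusters 6, 11 and 13, each had 8 detected endothelial markers and were left unnamed for their low depth. Of the unnamed barcodes, doublets included, 3473 had endothelial as the highest marker score and 334 cardiomyocyte, the next. The higher endothelial-like shares after CLP are therefore not set apart from fewer unnamed cells. The median depth of these unnamed cells was 1007 and 1152 UMIs in control and 1842 and 1411 at CLP 12h. At CLP 24h it was 1151 UMIs over 591 cells of replicate 1 and 5436 over 72 cells of replicate 2.

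By edgeR on the cells per class, 0 of the class shares passed the adjusted threshold in any of the 3 comparisons. At CLP 12h against control, 3 classes had an unadjusted p under 0.05. They were mesothelial-like (log2 fold change 5.08), endocardial-like (1.06) and neutrophil-like cells (2.40), each with adjusted p = 0.207 after Benjamini-Hochberg. Mesothelial-like cells numbered 4 and 0 in the control libraries and 23 and 103 in the CLP 12h libraries. At CLP 24h against control an unadjusted p under 0.05 was also found for T-like (3.17), NK-like (3.08) and dendritic-like cells (3.39), each with adjusted p = 0.258. CLP 24h replicate 2 carried most of these 3 rises. T-like cells were 0.244% and 0.224% of the control libraries, 0.784% of CLP 24h replicate 1 and 3.45% of CLP 24h replicate 2. NK-like cells were 0.0541% and 0.0320% of the control libraries, 0.151% of CLP 24h replicate 1 and 0.617% of CLP 24h replicate 2. Dendritic-like cells were 0.0406% and 0.0480% of the control libraries, 0.0754% of CLP 24h replicate 1 and 0.886% of CLP 24h replicate 2. Without CLP 24h replicate 2 the log2 fold changes were 1.74 (adjusted p = 0.26), 1.74 (0.28) and 0.75 (0.468). Between CLP 24h and CLP 12h an unadjusted p under 0.05 was found for fibroblast-like cells (-0.86, adjusted p = 0.612). DESeq2 on the same counts called 4 of these shares: mesothelial-like at CLP 12h, and T-like, NK-like and dendritic-like at CLP 24h. Without CLP 24h replicate 1, edgeR called 5 shares: higher dendritic-like and T-like and lower cardiomyocyte-like cells at CLP 24h against control, and higher dendritic-like and lower cardiomyocyte-like cells against CLP 12h. The cardiomyocyte-like fall was that of replicate 2 alone, with 7 such cells (0.111%), while replicate 1 at 2.25% lay above the controls at 1.38% and 1.14%. Without any other single library edgeR called 0 shares.

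**Figure D2:**
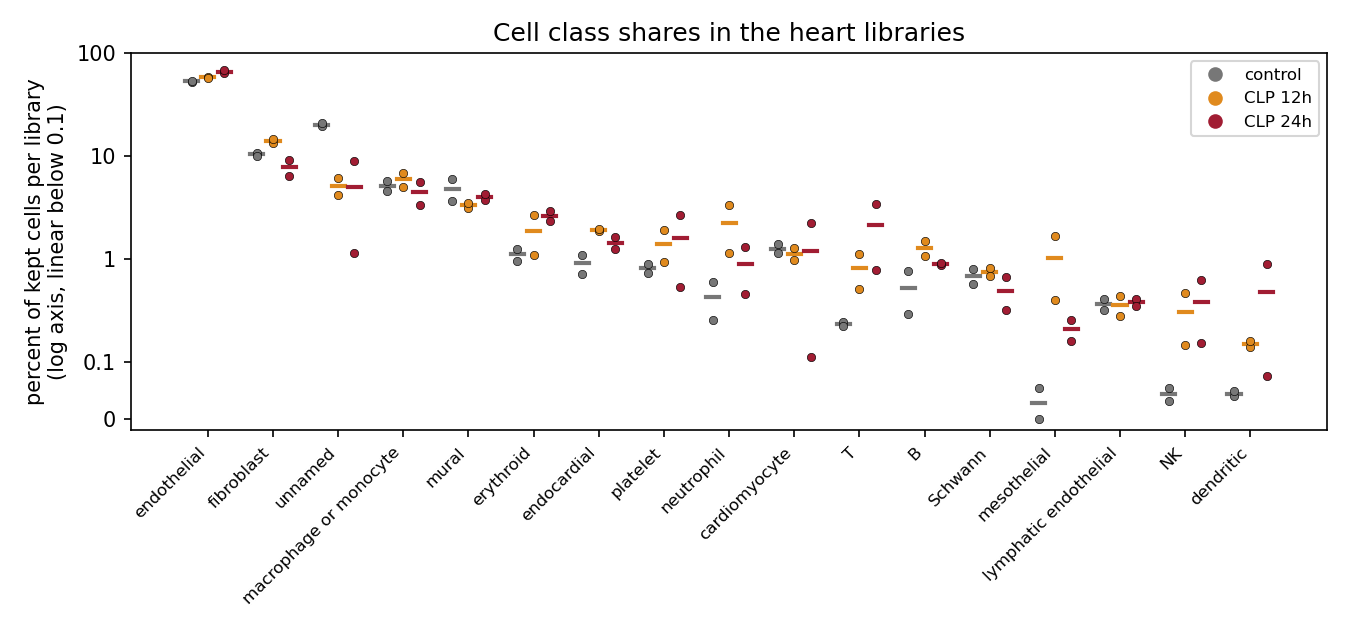
Percent of kept cells per library (y axis, log scale, linear below 0.1) in each cell class (x axis), 1 point per library coloured by group. Endothelial-like cells lead in all libraries, and neutrophil-like cells average 0.424% in control and 2.25% at CLP 12h.

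At CLP 12h, endothelial-like cells held a set of genes at high levels that were hardly found in control cells. Lcn2, an iron-binding acute phase protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, mm10), went from 1.86 ± 0.988 CPM in control to 2029.8 ± 1004 CPM, a log2 fold change of 10.10 ± 0.92 (SE, adjusted p = 0.000433). At CLP 12h this was under 0.1 of its level in neutrophil-like and in endocardial-like cells. The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by log2 10.06 and 8.43, with Mt1 going from 34.2 ± 1.27 to 11758 ± 2942 CPM. Inhbb, an activin subunit, rose by 8.90 (adjusted p = 3.26e-05) and the membrane protein gene Tmem252 by 8.79 (adjusted p = 9.26e-05). The largest fall among the genes that met the naming rule was that of Aqp7, a glycerol channel (ENSMUSG00000028427, chromosome 4, 41033074 to 41048139), from 440.1 ± 51.6 to 7.39 ± 5.05 CPM (log2 fold change -5.90, adjusted p = 0.000395). Mmp15, a membrane-bound matrix protease, fell by a log2 fold change of -5.03, Ckb, the brain-type creatine kinase, of -4.40, and the signalling adaptor Dok4, the retinoic acid receptor Rarg and the apelin receptor Aplnr of -3.89, -3.82 and -3.68.

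For each gene list, called members are counted over all genes, and again adjusted over the list alone where that changed a count. The count with library sizes alone is added where it differs by 3 genes or more. Counted in this way, the acute phase and metal binding genes moved most clearly in endothelial-like cells at CLP 12h: 11 of 13 tested members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.03e-05). This list and the others that camera called in this comparison had adjusted p = 0.751 with an estimated correlation, so none was called then. Slc39a14, a zinc and iron importer, rose by log2 4.29. Of the inflammatory cytokines and chemokines, 8 of 16 tested members rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0333). Among them were the neutrophil attractants Cxcl2 (4.78) and Cxcl1 (2.48). Of the NF-kB feedback genes, 7 of 12 tested members rose and 0 fell (camera adjusted p = 0.0327). Among them were the inhibitor Nfkbia (from 556 ± 28.5 to 2309 ± 391 CPM, log2 fold change 2.05, adjusted p = 0.000295), Birc3 (2.46) and Bcl3 (1.59). The interferon-stimulated genes went the other way: 0 of 20 tested members rose and 8 fell (0 and 13 with library sizes alone, camera adjusted p = 0.0327), with Oasl2 (-2.20) and Usp18 (-1.47) as examples. By fry 8 lists were called higher and 0 lower in this comparison, so fry did not call the interferon-stimulated list lower. Of the glucocorticoid response genes, 5 of 10 tested members rose and 0 fell (camera adjusted p = 0.0327). They were led by Fkbp5 (3.81) and Per1 (2.45). Of the oxidative stress and iron genes, 6 of 12 tested members rose and 1 fell (camera adjusted p = 0.0333). Of the immediate early and dissociation stress genes, 6 of 16 tested members rose and 0 fell (3 and 1 with library sizes alone, camera adjusted p = 0.0327). Among them was the heat shock gene Hspa1a (1.32). The median log2 fold change of the immediate early list was 0.29, and -0.08 with library sizes alone.

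For part of the genes of energy metabolism the counts in the same comparison depended on the scaling. Of the nuclear oxidative phosphorylation genes, 12 of 22 tested members rose and 1 fell (camera adjusted p = 0.0327), whereas 2 rose and 3 fell with library sizes alone. Camera's call of this list and the next was lost at adjusted p = 0.751 with an estimated correlation. Of the mitochondrially encoded genes, 4 of 13 tested members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0327). The mitochondrial share of endothelial-like UMIs was 4.95% and 5.06% in control against 7.48% and 6.49% at CLP 12h. Of the fatty acid uptake and oxidation genes, 1 of 15 tested members rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.0981). Lpl, the lipase that frees fatty acids at the vessel wall, rose from 2049.8 ± 565 to 6331 ± 117 CPM (log2 fold change 1.63, adjusted p = 0.0011). The transcription factor Tcf15 (-1.64), the mitochondrial fatty acid enzyme Cpt1a (-1.38) and Acsl1 (-1.12) fell. Of the glycolysis genes, 6 of 15 tested members rose and 3 fell (camera adjusted p = 0.312), and 4 rose and 4 fell with library sizes alone. The activator Pfkfb3 (2.23) and the glucose importer Slc2a1 (2.06) rose and the enzyme gene Pfkl (-1.20) fell.

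The genes of the vessel wall itself were called in both directions in endothelial-like cells at CLP 12h, as were all tested genes, and camera called none of the lists that follow. Of the junction and barrier genes, 7 of 16 tested members rose and 4 fell (camera adjusted p = 0.537), and 3 rose and 7 fell with library sizes alone. The tight junction gene Cldn5 went from 829 ± 4.75 to 3880.1 ± 553 CPM (log2 fold change 2.23, adjusted p = 0.000227) and the sphingosine receptor S1pr1 rose by 1.43, whereas Tek, the angiopoietin receptor, fell with a log2 fold change of -1.07. Of the adhesion and activation genes, 3 of 10 tested members rose and 0 fell (camera adjusted p = 0.372). Of the coagulation and fibrinolysis genes, 5 of 11 tested members rose and 0 fell (camera adjusted p = 0.0997). The urokinase receptor Plaur went from 25.3 ± 0.442 to 968 ± 274 CPM (log2 fold change 5.26, adjusted p = 0.000316), and tissue plasminogen activator Plat rose by log2 1.82. Of the p53 targets, 7 of 11 tested members rose and 1 fell (camera adjusted p = 0.0857). The cell cycle inhibitor Cdkn1a went from 1262 ± 14.6 to 4178 ± 68.8 CPM (1.73). Of the extracellular matrix genes, 4 of 19 tested members rose and 3 fell (3 and 6 with library sizes alone, camera adjusted p = 0.731), with the basement membrane collagens Col4a1 (1.32) and Col4a2 (1.19) higher.

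In all, edgeR called 6983 of 13425 genes in endothelial-like cells at CLP 12h, 3539 higher and 3444 lower. With library sizes alone, which moved the median of all genes to -0.38 on the log2 scale, the split was 1762 higher and 4766 lower. Without control replicate 1, control replicate 2 or CLP 12h replicate 1 the count was 3834, 3966 and 4568. Of the 25 lists, camera called 9, each with adjusted p = 0.751 with an estimated correlation, and 5 without CLP 12h replicate 1. With so many single genes called, the counts of called members of a list are to be read against these totals, here and in the other comparisons. The control cells of this class came mostly from clusters 2 (48.4%) and 3 (41.8%), and the CLP 12h cells from clusters 0 (55.5%) and 4 (25.8%).

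Free RNA was checked with genes of other cells. A UMI of the neutrophil gene S100a8 was found in 23% of endothelial-like cells in CLP 12h replicate 1 and in at most 7.40% in the other libraries, against 94.7% or more of neutrophil-like cells. A UMI of the cardiomyocyte gene Myh6 was found in more of them, in 30.9% to 42.2% of endothelial-like cells over the 6 libraries. In fibroblast-like cells it was 10.7% to 14.9% and in macrophage or monocyte-like cells 15.7% to 24.9%, so RNA of other cells was present in these 3 classes. A UMI of Lcn2 was found in 0.954% and 1.34% of control endothelial-like cells, 72.2% and 51.2% at CLP 12h, and 73.3% and 90.7% at CLP 24h. In CLP 24h replicate 2, which held 29 neutrophil-like cells, S100a8 was found in 1.19% of endothelial-like cells, so free neutrophil RNA leaves most Lcn2-positive cells of that library unexplained. How much Lcn2 was free RNA of other classes, such as endocardial-like cells, was not measured. The median depths in CLP 12h replicate 1 were 6234 UMIs in endothelial-like and 6432 in neutrophil-like cells. Of the neutrophil granule genes, 4 of 5 tested members rose and 0 fell (camera adjusted p = 0.0617) in endothelial-like cells at CLP 12h, where Ngp stood at 2.97 ± 2.90 CPM, under 0.1 of its level in another class.

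Against control, acute phase genes, cytokines and NF-kB feedback genes were also higher in endothelial-like cells at CLP 24h. For some of them the CLP 24h libraries lay far apart: Lcn2 stood at 7577 ± 5857 CPM (log2 fold change 12.00 ± 0.98 SE, adjusted p = 0.000195). Csf3, the growth factor for neutrophils (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629), went from 0.156 ± 0.00530 CPM in control to 788 ± 693 CPM (log2 fold change 12.26, adjusted p = 0.000568). The Csf3 level of endothelial-like cells was under 0.1 of that of endocardial-like cells. Aqp7 stood at 3.32 ± 1.10 CPM (log2 fold change -7.03, adjusted p = 0.000178), and Aplnr, Ckb and Rarg had log2 fold changes of -4.82, -4.74 and -4.52. Of the inflammatory cytokines and chemokines, 14 of 16 tested members rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 0.00187). Like the other lists called at CLP 24h in this class, it had adjusted p = 0.682 with an estimated correlation. Cxcl2 stood at 3640.1 ± 1068 CPM (8.66) and Cxcl1 at 3674 ± 1164 CPM (5.80). Of the NF-kB feedback genes, 10 of 12 tested members rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 5.65e-05). Tnfaip3, a brake on NF-kB signalling, stood at 315 ± 14.0 CPM against 6.99 ± 0.490 in control (log2 fold change 5.49, adjusted p = 0.000238). Of the acute phase and metal binding genes, 12 of 13 tested members rose and 0 fell (camera adjusted p = 4.43e-05), with Mt2 at log2 10.19.

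Icam1, an adhesion molecule that holds white cells to the vessel wall, was higher at CLP 24h in endothelial-like cells. It went from 302 ± 34.7 to 1231 ± 71.7 CPM (log2 fold change 2.03, adjusted p = 0.000859). Of the whole adhesion and activation list, 6 of 10 tested members rose and 2 fell (camera adjusted p = 0.145). Of the p53 targets, 7 of 11 tested members rose and 0 fell (7 and 1 adjusted over the list alone, 4 and 3 with library sizes alone, camera adjusted p = 0.0492). Like every other list that camera called in this comparison, it had adjusted p = 0.682 with an estimated correlation. Among its members were Cdkn1a (1.88), Fas (1.96) and Mdm2 (1.62). Of the immediate early and dissociation stress genes, 11 of 16 tested members rose and 1 fell (5 and 4 with library sizes alone, camera adjusted p = 0.026). The interferon-stimulated genes divided: 4 of 20 tested members rose and 6 fell (4 and 5 adjusted over the list alone, 2 and 11 with library sizes alone, camera adjusted p = 0.445), with Ifit1 (-2.02) and Usp18 (-1.76) lower. Of the nuclear oxidative phosphorylation genes, 10 of 22 tested members rose and 1 fell (camera adjusted p = 0.0492), but 1 rose and 7 fell with library sizes alone. Of the mitochondrially encoded genes, 8 of 13 tested members rose and 0 fell (3 and 0 with library sizes alone, camera adjusted p = 0.0317). The mitochondrial share of endothelial-like UMIs was 4.83% and 9.73%, the former below both controls. Cldn5 stood at 6621 ± 446 CPM (3.0), Lpl at 6578 ± 447 CPM (1.68) and Col4a1 at 3311 ± 14.1 CPM (1.80). Of the MHC class I genes, 5 of 11 tested members rose and 0 fell (1 and 1 with library sizes alone, camera adjusted p = 0.184), with the peptide transporter Tap1 at log2 1.74. Of the inflammasome and necroptosis genes, 4 of 10 tested members rose and 1 fell (camera adjusted p = 0.22), with the inflammatory caspase Casp4 at 3.0.

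edgeR called 7947 genes in endothelial-like cells at CLP 24h, 3935 higher and 4012 lower; with library sizes alone, which put the median of all genes at -0.54, the split was 1867 and 5954. Without control replicate 1 or control replicate 2 the count was 5243 and 5279. camera called 7 of the 25 lists, each with adjusted p = 0.682 with an estimated correlation. The CLP 24h cells came from clusters 1 (45.7%), 0 (19.1%), 7 (15.3%) and 4 (12.3%), and cluster 1 held mostly cells of CLP 24h replicate 2.

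**Figure D3:**
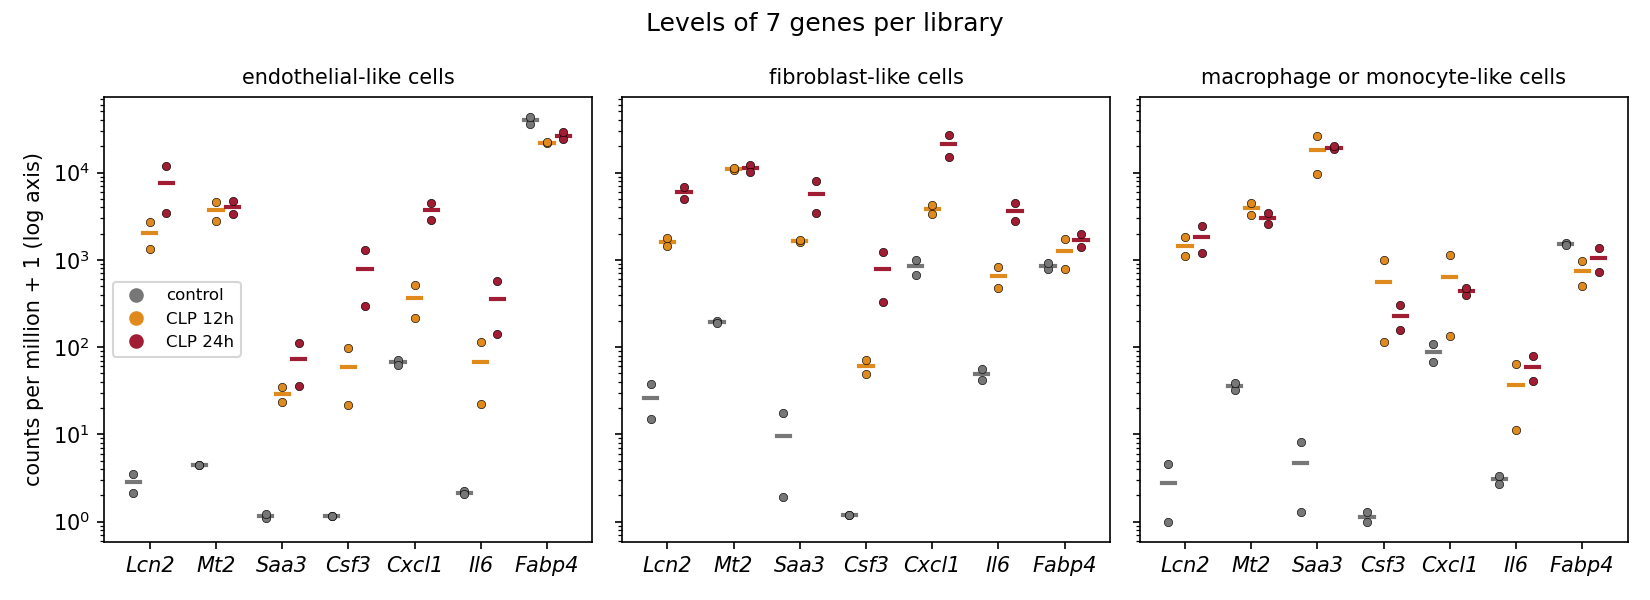
CPM plus 1 (y axis, log scale) of 7 genes (x axis) in endothelial-like, fibroblast-like and macrophage or monocyte-like cells, 1 point per library coloured by group, with the mean as a bar. Lcn2 in endothelial-like cells goes from a mean of 1.86 CPM in control to 7577 at CLP 24h.

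In fibroblast-like cells at CLP 12h the acute phase genes Saa3 and Lcn2 and the chemokine Cxcl2 were among the largest rises. Saa3, a serum amyloid A protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), went from 8.70 ± 11 to 1626 ± 66.6 CPM (log2 fold change 7.55 ± 0.99 SE, adjusted p = 0.000463), under 0.1 of its level in macrophage or monocyte-like cells, and Saa1 rose by 7.10. Lcn2 rose by 5.98 to 1603 ± 212 CPM and Csf3 by 8.08 to 59.7 ± 15.4 CPM, each under 0.1 of its level in another class. Mcoln2, an endolysosomal channel, went from 1.12 ± 0.304 to 140.2 ± 14.5 CPM (log2 fold change 6.95, adjusted p = 5.92e-06). Cxcl2 went from 5.05 ± 4.16 to 379 ± 187 CPM (log2 fold change 6.23, adjusted p = 0.000418). Among the largest falls were those of Tril, a Toll-like receptor partner, from 73.2 ± 1.54 to 3.73 ± 1.43 CPM (log2 fold change -4.28, adjusted p = 1.68e-05), and of Ahnak2 (-3.71), the Wnt pathway gene Dact3 (-3.31) and Selenbp1 (-3.22). Slc9a3r2 also fell (-4.01), at under 0.1 of its level in another class.

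Every tested NF-kB feedback gene rose in fibroblast-like cells at CLP 12h: 10 of 10 tested members rose and 0 fell (camera adjusted p = 8.5e-06). It and the other lists called here had adjusted p = 0.779 with an estimated correlation, so none was called then. Among the risen genes were Bcl3 (3.47), Tnfaip3 (3.61) and Birc3 (2.94). Of the inflammatory cytokines and chemokines, 13 of 16 tested members rose and 0 fell (9 and 0 with library sizes alone, camera adjusted p = 0.00529). Interleukin 6 (Il6) went from 47.8 ± 10.1 to 654 ± 247 CPM (log2 fold change 3.77, adjusted p = 9.2e-05) and Cxcl1 to 3772 ± 659 CPM (2.17). Of the acute phase and metal binding genes, 12 of 13 tested members rose and 0 fell (camera adjusted p = 7.89e-06), with Mt2 (5.81) and Slc39a14 (4.93). Of the oxidative stress and iron genes, 8 of 12 tested members rose and 0 fell (camera adjusted p = 0.00529). Mitochondrial superoxide dismutase Sod2 went from 66.8 ± 0.157 to 1302 ± 3.88 CPM (log2 fold change 4.29, adjusted p = 9.74e-06) and the thioredoxin reductase Txnrd1 rose by 3.11. Of the glucocorticoid response genes, 9 of 10 tested members rose and 1 fell (4 and 1 with library sizes alone, camera adjusted p = 0.00853), with Per1 (2.43) and Sgk1 (1.58). Of the nuclear oxidative phosphorylation genes, 11 of 22 tested members rose and 1 fell (camera adjusted p = 0.00853), but 5 rose and 5 fell with library sizes alone. Of the mitochondrially encoded genes, 7 of 13 tested members rose and 0 fell (10 and 0 adjusted over the list alone, 3 and 0 with library sizes alone, camera adjusted p = 0.00853). The mitochondrial share of fibroblast-like UMIs was 4.93% and 4.82% in control and 6.39% and 5.48% at CLP 12h. Of the immediate early and dissociation stress genes, 6 of 16 tested members rose and 0 fell (camera adjusted p = 0.0479), with a median log2 fold change of 0.37, or -0.03 with library sizes alone.

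For the matrix genes that define fibroblasts the counts depended on the scaling. Of the extracellular matrix list, 3 of 20 tested members rose and 4 fell (3 and 2 adjusted over the list alone, 3 and 10 with library sizes alone, camera adjusted p = 0.775) at CLP 12h. At CLP 24h 3 of 20 tested members rose and 4 fell (3 and 15 with library sizes alone, camera adjusted p = 0.627). Its medians were -0.19 and -0.29, or -0.59 and -0.83 with library sizes alone, while fry read the list as up (adjusted p = 0.693 and 0.433). Lox, the collagen cross-linking enzyme, went from 68.5 ± 9.21 CPM in control to 338 ± 13 and 495 ± 12.6 CPM (log2 fold change 2.30 and 2.85, adjusted p = 1.88e-05 and 6.69e-06), and Col4a1 rose by 1.14 and 1.72. Elastin (Eln) went from 393 ± 114 to 72.1 ± 11.7 and 96.1 ± 58.6 CPM (-2.44 and -2.03).

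At CLP 24h Cxcl2, Cxcl3, Il6, Cxcl1, Lif and Csf2 stood far above control in fibroblast-like cells. Cxcl2 reached 8334 ± 6224 CPM (log2 fold change 10.69, adjusted p = 4.97e-05), and Cxcl3, without a UMI in the control fibroblast-like cells, was at least 642.6-fold higher, with the floor set at 3 UMIs over the group. Il6 reached 3633 ± 1238 CPM (log2 fold change 6.25 ± 0.39 SE), Cxcl1 21201 ± 8523 CPM (4.66), and the leukemia inhibitory factor gene Lif 389 ± 238 CPM (8.24). The myeloid growth factor Csf2 went from 0.205 ± 0.290 to 168 ± 203 CPM (log2 fold change 9.57, adjusted p = 0.00134). Among the genes that met the naming rule the largest fall was that of Inmt, a methyltransferase, from 186 ± 25.3 to 4.16 ± 0.0756 CPM (log2 fold change -5.48, adjusted p = 5.13e-06), followed by Tril (-5.45), Selenbp1 (-5.18) and Ahnak2 (-5.13). Of the inflammatory cytokines and chemokines, 15 of 16 tested members rose and 0 fell (camera adjusted p = 1.27e-05). It and the other lists called at CLP 24h had adjusted p = 0.724 with an estimated correlation. Of the NF-kB feedback genes, 10 of 10 tested members rose and 0 fell (camera adjusted p = 1.46e-06). Of the acute phase and metal binding genes, 10 of 13 tested members rose and 0 fell (camera adjusted p = 8.51e-06). Of the MHC class I genes, 7 of 11 tested members rose and 0 fell (camera adjusted p = 0.0753). H2-D1 went from 1097 ± 393 to 3417 ± 1456 CPM (log2 fold change 1.64, adjusted p = 0.00334) and Tap1 rose by log2 2.09. Of the glycolysis genes, 7 of 15 tested members rose and 3 fell (camera adjusted p = 0.126), and 5 rose and 7 fell with library sizes alone. Lactate dehydrogenase Ldha stood at 730.0 ± 61.5 CPM (2.02) and hexokinase Hk2 also rose (2.45). Of the p53 targets, 8 of 11 tested members rose and 1 fell (8 and 2 adjusted over the list alone, 5 and 3 with library sizes alone, camera adjusted p = 0.0776), with Cdkn1a at 1.87 and Trp53inp1 at 1.94. Of the oxidative stress and iron genes, 9 of 12 tested members rose and 0 fell (7 and 3 with library sizes alone, camera adjusted p = 0.012). Of the mitochondrially encoded genes, 10 of 13 tested members rose and 0 fell (4 and 0 with library sizes alone, camera adjusted p = 0.011). The mitochondrial share of fibroblast-like UMIs was 4.60% and 7.39% at CLP 24h against 4.93% and 4.82% in control, so replicate 1 lay below both controls. Of the nuclear oxidative phosphorylation genes, 11 of 22 tested members rose and 1 fell (camera adjusted p = 0.0122), but 6 rose and 8 fell with library sizes alone.

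edgeR called 7356 of 12543 genes in fibroblast-like cells at CLP 12h (3732 higher, 3624 lower) and 7936 at CLP 24h (3936 and 4000). With library sizes alone, where the median of all genes was -0.42 and -0.62, the splits were 2103 and 5483, and 2083 and 6284. camera called 8 lists at CLP 12h, each with adjusted p = 0.779 with an estimated correlation, and 6 at CLP 24h, each with adjusted p = 0.724 with an estimated correlation. Without CLP 24h replicate 1 the latter count was 11. Control fibroblast-like cells lay in cluster 9 (94.3%) and the CLP cells in cluster 5 (94.8% and 92.2%).

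In macrophage or monocyte-like cells at CLP 12h, Saa3 went from 3.70 ± 4.83 to 17933 ± 11633 CPM (log2 fold change 12.15 ± 1.05 SE, adjusted p = 0.000701). The chemokine Cxcl3 went from 0.527 ± 0.0738 to 289.6 ± 365 CPM (log2 fold change 9.01, adjusted p = 0.00704). The cystine importer Slc7a11 went from 2.59 ± 2.03 to 427 ± 444 CPM (log2 fold change 7.28, adjusted p = 0.00327). Lcn2 (9.54) and Tmem252 (7.18) also rose, each at under 0.1 of its level in another class. Among the largest falls were Cmah, a sialic acid enzyme (ENSMUSG00000016756, chromosome 13, 24327404 to 24477377), from 87.4 ± 26.6 to 0.940 ± 0.266 CPM (log2 fold change -6.44, adjusted p = 0.000505), and the lysophospholipid receptor Gpr34, from 99.7 ± 28.0 to 1.32 ± 0.265 CPM (log2 fold change -6.23, adjusted p = 0.000352). Others were the signalling gene Rasgrp3 (-6.17), the MHC class II activator Ciita (-5.36), Rnf150 (-4.95) and the interferon-induced Ifit3b (-4.93).

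Most tested genes of resident heart macrophages were called lower and most of recruited monocytes higher at CLP 12h. Of the resident macrophage genes, 0 of 13 tested members rose and 7 fell (camera adjusted p = 0.00324). No list of this class was called with an estimated correlation: those that camera called had adjusted p = 0.482 to 0.594 with an estimated correlation at CLP 12h. The fractalkine receptor Cx3cr1 went from 231 ± 35.2 to 15.1 ± 0.142 CPM (log2 fold change -3.93, adjusted p = 0.00104). Timd4, a receptor for dying cells, went from 85.1 ± 2.35 to 23.6 ± 2.54 CPM (-1.85), and Maf and Igf1 changed by -2.18 and -2.45. Of the recruited monocyte genes, 8 of 12 tested members rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000743), with Chil3 (3.27), Thbs1 (6.43) and Vcan (5.61). Control cells of this class came from clusters 18 (71.9%), 32 (16.6%) and 24 (10.2%), and CLP 12h cells from clusters 12 (64.0%), 26 (19.1%) and 24 (16.8%). Clusters 18 and 32 held 1 and 0 CLP 12h cells, so a change of the mix of cells is not set apart from a change within cells. Cluster 12 had Mrc1, Retnla and Cd163 of the resident list among its leading 10 genes. Of the interferon-stimulated genes, 0 of 20 tested members rose and 12 fell (0 and 13 adjusted over the list alone, camera adjusted p = 2.97e-05). Ifit3 went from 347 ± 98.8 to 31.7 ± 5.0 CPM (log2 fold change -3.44, adjusted p = 0.00156), with lower Oasl2 (-3.01) and Ifit2 (-2.82). Of the MHC class II genes, 0 of 7 tested members rose and 3 fell (0 and 4 adjusted over the list alone, 0 and 6 with library sizes alone, camera adjusted p = 0.0057), with H2-DMa (-1.64) and H2-DMb1 (-2.37) lower. Of the MHC class I genes, 0 of 11 tested members rose and 7 fell (camera adjusted p = 0.0184), with the immunoproteasome subunit Psmb9 at -1.70. Of the immediate early and dissociation stress genes, 0 of 16 tested members rose and 7 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.0288), with Atf3 at -1.50. Of the fatty acid uptake and oxidation genes, 0 of 15 tested members rose and 6 fell (0 and 9 with library sizes alone, camera adjusted p = 0.00374), with the mitochondrial fatty acid enzyme Cpt1a at -1.70.

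The rising lists of macrophage or monocyte-like cells at CLP 12h were led by acute phase genes. Of the acute phase and metal binding genes, 13 of 14 tested members rose and 0 fell (camera adjusted p = 7.73e-09). As above, the called lists had adjusted p = 0.482 to 0.594 with an estimated correlation. Mt1 reached 12542 ± 4007 CPM (4.42) and Mt2 rose by 6.80. Among NF-kB feedback genes, 9 of 12 tested members rose and 0 fell (camera adjusted p = 0.000415), with Tnfaip3 (2.94) and Tnip1 (2.96). Among inflammatory cytokines and chemokines, 9 of 16 tested members rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.00214). The interleukin 1 antagonist Il1rn went from 25.7 ± 22.0 to 668 ± 532 CPM (log2 fold change 4.68, adjusted p = 0.00686). Of the glycolysis genes, 9 of 15 tested members rose and 1 fell (6 and 1 with library sizes alone, camera adjusted p = 0.00736), with Pfkfb3 (3.07) and pyruvate kinase Pkm (1.83). Of the oxidative stress and iron genes, 6 of 11 tested members rose and 1 fell (camera adjusted p = 0.0109). The ferritin heavy chain Fth1 reached 37701 ± 22970.4 CPM (2.81). Of the proliferation genes, 8 of 16 tested members rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0207). The cycling marker Mki67 went from 8.34 ± 5.65 to 84.1 ± 32.4 CPM (log2 fold change 3.29, adjusted p = 0.00327). Cluster 30, which proliferation genes led, was left unnamed and so out of this class. It held 22 and 7 cells of the control and 36 and 13 of the CLP 12h libraries. How many of these were macrophage or monocyte-like was not tested. Of the nuclear oxidative phosphorylation genes, 9 of 22 tested members rose and 0 fell (camera adjusted p = 0.000701), and 2 rose and 0 fell with library sizes alone. Of the glucocorticoid response genes, 6 of 10 tested members rose and 0 fell (camera adjusted p = 0.0358). Of the mitochondrially encoded genes, 3 of 13 tested members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00822). The mitochondrial share of UMIs in this class was 6.65% and 6.08% in control and 7.02% and 6.87% at CLP 12h. Of the inflammasome and necroptosis genes, 3 of 11 tested members rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.545). Nlrp3 rose (2.42) while Gsdmd (-1.44) and Il18 (-1.19) fell.

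At CLP 24h the macrophage or monocyte-like cells held Saa3 at 19298 ± 1262 CPM (log2 fold change 12.26 ± 1.05 SE, adjusted p = 0.000588). The chemokine Ccl17, without a UMI in the control cells of this class, was at least 144.5-fold higher (floor of 3 UMIs over the group), at under 0.1 of its level in another class. Gpr34 (-6.58), Rnf150 (-5.90) and the lipid enzyme genes Pla2g2d (-5.79) and Hpgd (-5.66) were among the largest falls, Hpgd at under 0.1 of its level in another class. Of the resident macrophage genes, 0 of 13 tested members rose and 8 fell (0 and 12 adjusted over the list alone, 0 and 11 with library sizes alone, camera adjusted p = 2.2e-06). The lists called at this time had adjusted p = 0.654 to 0.687 with an estimated correlation. The CLP 24h cells of this class came from clusters 12 (70.1%), 26 (20.5%) and 24 (9.39%), with 0 in clusters 18 and 32, which held most control cells of the class, so a change of the mix of cells is not set apart from a change within cells. Resident genes that fell were Igf1 (-4.22), the bridging protein Gas6 (-4.53) and Cx3cr1 (-5.18). Of the recruited monocyte genes, 8 of 12 tested members rose and 0 fell (camera adjusted p = 0.00077). Ly6c2 went from 98.5 ± 31.3 to 652 ± 324 CPM (log2 fold change 2.73, adjusted p = 0.00249). Of the interferon-stimulated genes, 3 of 20 tested members rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.197). Of the MHC class II genes, 0 of 7 tested members rose and 3 fell (camera adjusted p = 0.339). The median of the latter was 0.11, its mean -1.11, and camera read it as down. Of the acute phase and metal binding genes, 12 of 14 tested members rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.56e-07). Among NF-kB feedback genes, 10 of 12 tested members rose and 0 fell (10 and 1 adjusted over the list alone, 7 and 2 with library sizes alone, camera adjusted p = 0.00077). Among inflammatory cytokines and chemokines, 10 of 16 tested members rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.000878), with Il1rn at 5.26. Of the glycolysis genes, 8 of 15 tested members rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00152). Of the proliferation genes, 8 of 16 tested members rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.012). Cluster 30 was left out here too, with 28 and 49 cells of the CLP 24h libraries. Of the immediate early and dissociation stress genes, 0 of 16 tested members rose and 8 fell (camera adjusted p = 0.00077), with Fosb at -2.71 and Egr1 at -2.24. Of the nuclear oxidative phosphorylation genes, 8 of 22 tested members rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000579), and 4 rose and 1 fell with library sizes alone.

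edgeR called 3554 of 10572 genes in this class at CLP 12h (1708 higher, 1846 lower) and 3867 at CLP 24h (1835 and 2032). With library sizes alone, where the median of all genes was -0.31 and -0.24, the splits were 964 and 2622, and 1188 and 2627. At CLP 12h the count was 1216 without control replicate 1, 1491 without control replicate 2 and 1874 without CLP 12h replicate 1. At CLP 24h it was 1615 and 1859 without each control, and 2174 without CLP 24h replicate 2. camera called 16 lists at CLP 12h, with adjusted p = 0.482 to 0.594 with an estimated correlation, and 9 at CLP 24h (14 without CLP 24h replicate 2), with adjusted p = 0.654 to 0.687 with an estimated correlation.

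**Figure D4:**
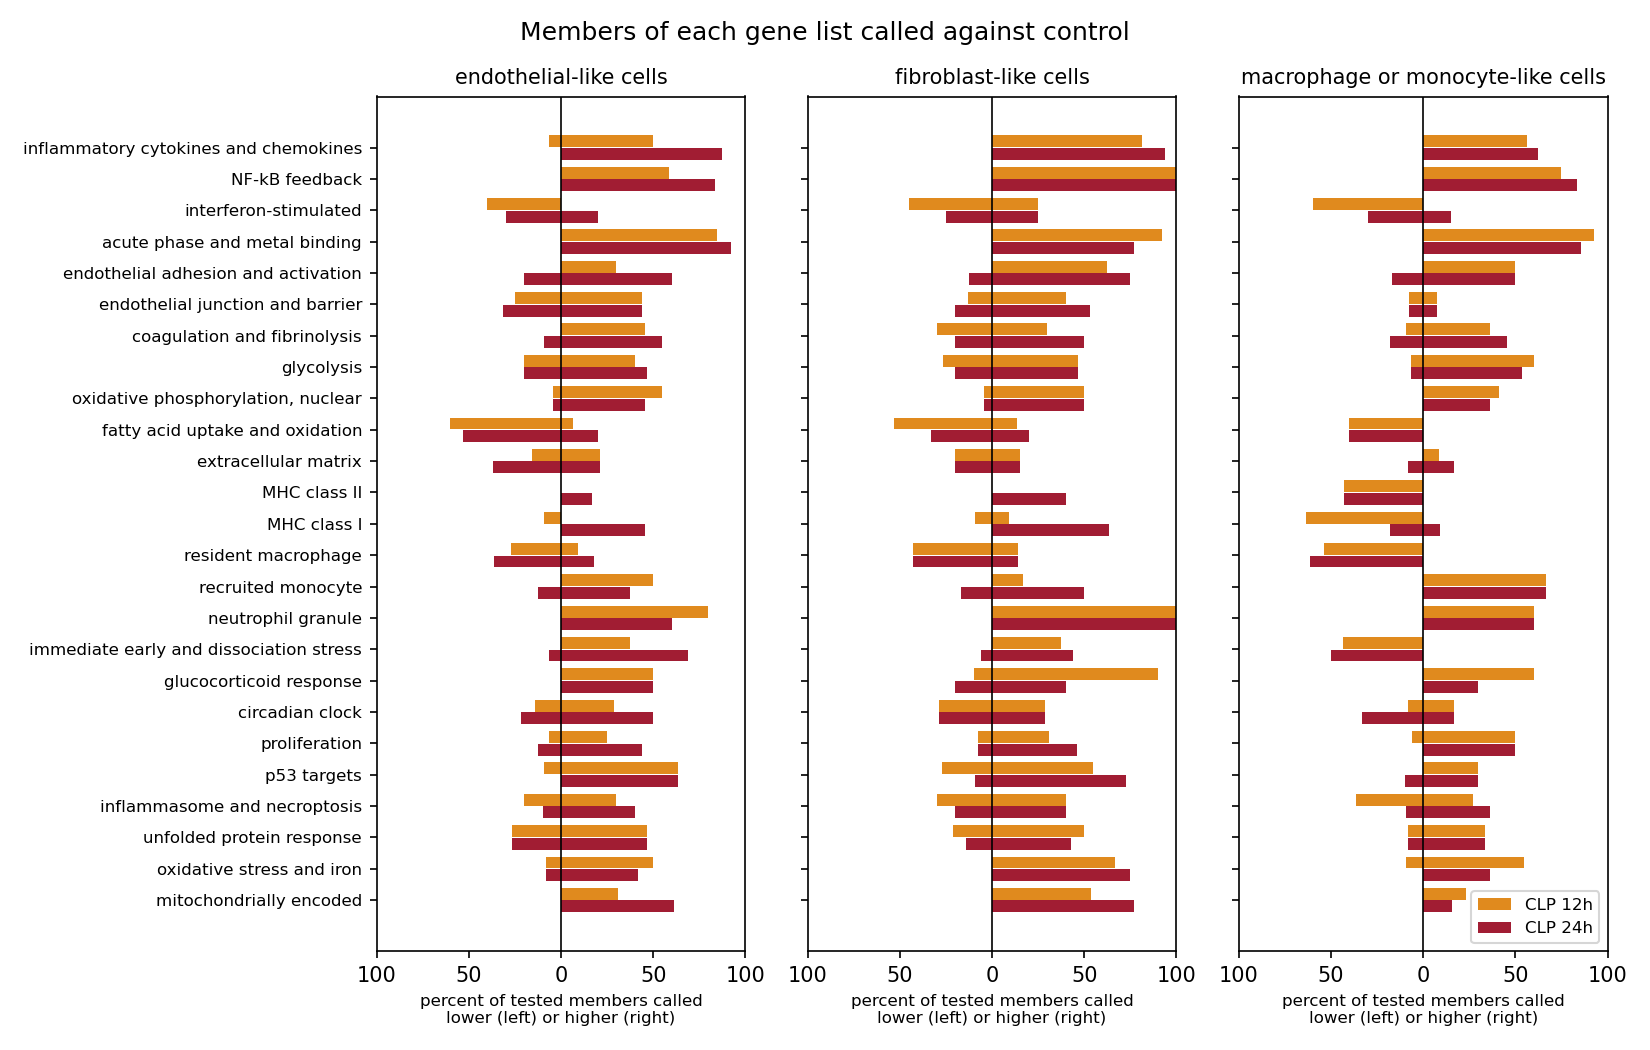
Percent of the tested members of each gene list (y axis) called lower (left) or higher (right) than control (x axis, percent), by bars for CLP 12h and CLP 24h in 3 cell classes. All 10 tested NF-kB feedback genes of fibroblast-like cells lie on the higher side, and 12 of 20 interferon-stimulated genes of macrophage or monocyte-like cells on the lower side at CLP 12h.

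Between CLP 24h and CLP 12h few single genes differed in endothelial-like cells and none passed in macrophage or monocyte-like cells, while more were called in fibroblast-like cells. In endothelial-like cells the chemerin receptor homolog Ccrl2 (ENSMUSG00000043953, chromosome 9, 111054486 to 111057519) went from 60.3 ± 1.29 CPM at CLP 12h to 495 ± 82.4 CPM at CLP 24h (log2 fold change 3.04 ± 0.17 SE, adjusted p = 0.00608). Birc2, an inhibitor of apoptosis, went from 84.2 ± 4.31 to 308 ± 14.0 CPM (log2 fold change 1.87, adjusted p = 0.00608). The homeodomain gene Hopx went from 272 ± 27.5 to 1060.4 ± 139.9 CPM (log2 fold change 1.96, adjusted p = 0.0193), and Slc26a10 from 73.6 ± 9.25 to 16.8 ± 0.483 CPM (log2 fold change -2.13, adjusted p = 0.00608). Among NF-kB feedback genes, 1 of 12 tested members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.08e-14). Both this list and the next had adjusted p = 0.814 with an estimated correlation; fry called 0 lists in this comparison, and camera called 9, or 4 without CLP 24h replicate 2. Among inflammatory cytokines and chemokines, 0 of 16 tested members rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 7.39e-09). edgeR called 10 genes, 9 higher and 1 lower, and 1743 had an unadjusted p under 0.05. This count moved with the settings: DESeq2 called 421, and without CLP 24h replicate 1 edgeR called 867, without CLP 12h replicate 2 it called 0, and without CLP 12h replicate 1 or either control 1. Over the alternatives the adjusted p of Ccrl2 ran from 1.74e-51 to 0.153 and that of Hopx from 2.89e-23 to 0.234.

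In fibroblast-like cells Csf2, Cxcl2, Lif and Ccl2 were higher at CLP 24h than at CLP 12h, but each of these calls was lost when some single library was left out. Csf2 went from 0.517 ± 0.731 to 168 ± 203 CPM (log2 fold change 8.31, adjusted p = 0.0313) and Cxcl2 from 379 ± 187 to 8334 ± 6224 CPM (log2 fold change 4.46, adjusted p = 0.0199). Lif went from 21.0 ± 6.64 to 389 ± 238 CPM (log2 fold change 4.21, adjusted p = 0.0109) and the monocyte attractant Ccl2 from 599 ± 71.3 to 10716 ± 6711 CPM (log2 fold change 4.16, adjusted p = 0.0122). The lipid transporter Abca8a (-2.15), the glutathione transferase Gsta3 (-2.06) and the angiopoietin-like genes Angptl2 (-2.03) and Angptl7 (-1.77) were lower. Among inflammatory cytokines and chemokines, 11 of 16 tested members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.57e-12). The lists called between the CLP groups had adjusted p = 0.681 to 0.713 with an estimated correlation, and fry called 0. Among NF-kB feedback genes, 4 of 10 tested members rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 3.91e-09). One of them was Tnfaip3 (log2 fold change 2.11, adjusted p = 0.0109). Of the glucocorticoid response genes, 0 of 10 tested members rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0115). edgeR called 526 genes (265 higher, 261 lower), with a split of 156 and 460 with library sizes alone. Leaving out 1 library gave 5 genes (CLP 12h replicate 1), 9 (CLP 12h replicate 2), 137 (control replicate 1), 143 (control replicate 2), 239 (CLP 24h replicate 2) and 1539 (CLP 24h replicate 1). Over the alternatives the adjusted p of Csf2 ran from 0.000136 to 0.18, that of Cxcl2 from 0.000426 to 0.141, that of Lif from 3.53e-09 to 0.0829, that of Ccl2 from 4.17e-09 to 0.108 and that of Gsta3 from 1.7e-23 to 0.0471.

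In macrophage or monocyte-like cells edgeR called 0 genes between the CLP groups; 711 had an unadjusted p under 0.05, DESeq2 called 45, and edgeR called 6 without CLP 24h replicate 1. By camera the interferon-stimulated genes stood higher at CLP 24h than at CLP 12h in this class (median log2 fold change 1.10, adjusted p = 5.06e-19; adjusted p = 0.203 with an estimated correlation). Of them, 14 of 20 members were called adjusted over the list alone. MHC class I genes (median 0.70) also stood higher and resident macrophage genes (median -1.25) lower, with adjusted p = 0.357 and adjusted p = 0.203 with an estimated correlation. In all, camera called 9 lists in endothelial-like cells (4 without CLP 24h replicate 2), each with adjusted p = 0.814 with an estimated correlation. It called 10 in fibroblast-like cells, with adjusted p = 0.681 to 0.713 with an estimated correlation, and 7 in macrophage or monocyte-like cells (12 and 13 without each CLP 12h library), with adjusted p = 0.203 to 0.639 with an estimated correlation.

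Mural-like and erythroid-like cells also had enough cells for a test. In mural-like cells, which wrap small vessels, edgeR called 3662 genes at CLP 12h (1802 higher, 1860 lower), 4623 at CLP 24h (2291 and 2332) and 4 between the CLP groups. In erythroid-like cells it called 1948 (974 and 974), 2706 (1317 and 1389) and 18. Both classes carried endothelial RNA: the endothelial cadherin Cdh5 stood at 766 ± 37.2 unscaled CPM in control mural-like and 870.0 ± 59.9 in control erythroid-like cells, against 1357 ± 41.0 in endothelial-like and 32.6 ± 1.34 in fibroblast-like cells. Each control library weighed on these counts: without control replicate 1 they were 919 and 1962 in mural-like and 627 and 1145 in erythroid-like cells at CLP 12h and CLP 24h. Without control replicate 2 they were 1111, 2198, 620 and 1032. At CLP 12h the counts without CLP 12h replicate 1 were 1083 and 772, and the mural-like count was 1276 without CLP 12h replicate 2. Between the CLP groups the mural-like count was 0 without either control or either CLP 12h library, 778 without CLP 24h replicate 1 and 46 without CLP 24h replicate 2. The erythroid-like count was 4 without either control, 5 without either CLP 12h library, 290 without CLP 24h replicate 1 and 71 without CLP 24h replicate 2. The mural-like cells of the controls lay mostly in cluster 15 (80.3%) and those of the CLP groups in cluster 10 (98.8% at CLP 12h). This class joins pericytes and smooth muscle cells. Cluster 15 had the pericyte markers Vtn, Kcnj8, Abcc9 and Notch3 among its leading 10 genes. Cluster 10 had the smooth muscle markers Tagln, Myh11 and Acta2 there, beside the pericyte markers Pdgfrb and Rgs5. The erythroid-like cells of the controls lay mostly in cluster 34 (75.8%) and those of the CLP groups in cluster 16. In both classes a change of the mix of cells is therefore not set apart from a change within cells.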

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

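The tests of the barcodes over 20% mitochondrial UMIs were chosen after the result was seen, and the other tests of explanations below before it.

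Genes that differed between the CLP times. In endothelial-like cells the effects at CLP 24h and CLP 12h differed by log2 3.04 for Ccrl2, 2.29 for Gem (a small GTPase, at under 0.1 of its level in another class), 1.96 for Hopx, 1.87 for Birc2 and -2.13 for Slc26a10. In fibroblast-like cells they differed by 8.31 for Csf2, 4.46 for Cxcl2, 4.21 for Lif and 4.16 for Ccl2, and by -2.15, -2.06, -2.03 and -1.77 for Abca8a, Gsta3, Angptl2 and Angptl7. Each difference was tested by edgeR as CLP 24h against CLP 12h. Of these 13 genes, Gsta3 kept an adjusted p under 0.05 without each library in turn. Without CLP 12h replicate 2 the adjusted p of Ccrl2, Gem, Hopx, Birc2 and Slc26a10 was 0.153, 0.153, 0.234, 0.172 and 0.146, and of Csf2, Cxcl2, Lif, Ccl2, Abca8a, Angptl2 and Angptl7 it was 0.18, 0.141, 0.077, 0.0895, 0.0726, 0.0766 and 0.0861.

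Genes that moved in opposite directions in 2 cell classes. The heat shock genes Hspa1a and Hspa1b and the immediate early genes Atf3 and Nr4a1 rose in endothelial-like or fibroblast-like cells and fell in macrophage or monocyte-like cells. The macrophage effect minus the endothelial effect was -2.31 at CLP 12h and -2.90 at CLP 24h for Hspa1a, and at CLP 24h -2.24 for Hspa1b, -2.80 for Atf3 and -1.87 for Nr4a1. The macrophage effect minus the fibroblast effect was -2.11 at CLP 12h and -3.09 at CLP 24h for Nr4a1, and -2.52 at CLP 24h for Hspa1a. Edn1, the vasoconstrictor endothelin 1, went the other way at CLP 24h, with differences of 6.77 from endothelial-like and 6.79 from fibroblast-like cells; in macrophage or monocyte-like cells it stood at 3.40 ± 3.58 CPM in control and 190.1 ± 174 CPM at CLP 24h. The inflammasome adaptor Pycard differed by 1.85 between macrophage or monocyte-like and endothelial-like cells at CLP 24h, and Tap1 by -2.22 between macrophage or monocyte-like and fibroblast-like cells at CLP 12h. Acsl1, which activates fatty acids, rose in fibroblast-like and fell in endothelial-like cells, with differences of 1.91 at CLP 12h and 2.12 at CLP 24h, and the protein-folding enzyme Pdia6 differed by 0.70 at CLP 24h. Pdia6 rose by only 0.41 in fibroblast-like cells and changed by -0.33 in endothelial-like cells, and Nr4a1 rose by 0.38 in endothelial-like cells at CLP 24h. These 2 rises are smaller than the fall of the median of all genes with library sizes alone, given above. The opposite directions of Pdia6, and of Nr4a1 against endothelial-like cells, therefore depended on the scaling. edgeR called each of these differences, with adjusted p up to 0.00697. The genes were picked because they were called in opposite directions in the 2 classes, which nearly decides this test: it called 162 of 163 such genes between endothelial-like and macrophage or monocyte-like cells at CLP 12h, and every one in the other 5 pairs of classes and times. No test compared whole gene lists between classes.

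The 2 CLP 24h libraries lay apart in their endothelial-like genes, and not in these alone. Of the genes at 10.0 CPM or more, 358 were at least 2-fold apart between the CLP 24h libraries (288 higher in replicate 2), against 81 at CLP 12h and 13 in control. In fibroblast-like cells it was 246 at CLP 24h, 55 at CLP 12h and 33 in control, and in macrophage or monocyte-like cells 436, 483 and 201. The tests below cover the endothelial-like genes. RNA of T, NK and dendritic-like cells, which were more frequent in CLP 24h replicate 2, would need most of the genes higher in replicate 2 to be far higher in these classes, but only 6.60% of them stood under 0.1 of such a level. Damaged cells with a high mitochondrial share among the kept cells are argued against too. With the stricter cell filter the number apart was 107% of that with the main filter. Damage of other kinds was not tested, and the mitochondrial share of endothelial-like UMIs was 4.83% in replicate 1 and 9.73% in replicate 2. Cluster 1, with Cxcl9, Ubd and Ido1 among its leading 10 genes, held 7.56% of the endothelial-like cells of CLP 24h replicate 1 and 83.6% of replicate 2. No biological explanation was tested, as the labels give no difference between the 2 libraries.

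Interferon-stimulated genes were lower in macrophage or monocyte-like cells at CLP 12h, with a median log2 fold change of -1.24. They were not lower there alone: in endothelial-like cells 0 of 20 tested members rose and 8 fell (0 and 13 with library sizes alone), in mural-like cells 0 of 20 tested members rose and 12 fell, in erythroid-like cells 0 of 20 tested members rose and 11 fell (0 and 12 adjusted over the list alone) and in fibroblast-like cells 5 of 20 tested members rose and 9 fell (5 and 12 with library sizes alone). The medians were -0.73, -1.42, -1.14 and -0.33. In fibroblast-like cells camera called 0 lists lower at CLP 12h, so this list was not called there. By fry 0 lists were called lower in endothelial-like, fibroblast-like and erythroid-like cells at CLP 12h, against 1 in mural-like and 4 in macrophage or monocyte-like cells. The mural-like and erythroid-like cells carried endothelial RNA, with Cdh5 at 766 ± 37.2 and 870.0 ± 59.9 unscaled CPM in control against 1357 ± 41.0 in endothelial-like cells, so these 3 classes may share 1 signal. A few control cells with high interferon genes could give this, but without the 10% highest cells of each library the median was -1.30, or 105% of the value with all cells. A change of the mix of cells within the class cannot be told apart from a change within cells, because 0 clusters of the class held at least 20 cells in each control and CLP 12h library. The biological explanation, a lower interferon response 12 hours after CLP, may reach beyond this class and stays untested.

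More barcodes of the CLP libraries passed 20% mitochondrial UMIs, a signal in data the comparisons left out: 40.1% and 31.4% at CLP 12h, 25.9% and 44.4% at CLP 24h, 12.5% and 22.1% in control. Cardiomyocyte was the highest marker score in 20.7% ± 2.06 and 22.3% ± 3.61 of these CLP barcodes, against 1.87% ± 0.600 and 1.96% ± 1.86 of the kept ones, so this score was enriched; in the excluded control barcodes it was 18.1% ± 0.764. As the main source, fragments that carry cardiomyocyte transcripts are argued against: cardiomyocyte markers held on average 11.1% of the share of non-mitochondrial UMIs that they had in cardiomyocyte-like cells. Fragments with little RNA besides that of mitochondria were not tested. Damaged endothelial-like cells cannot be told apart from free endothelial RNA. The highest score was endothelial in 54.3% of these CLP barcodes, but also in 65.8% ± 0.438 and 74.2% ± 2.78 of the kept ones and 59.7% ± 3.05 of the excluded control barcodes, so the score does not tell what the added barcodes were. Whether sepsis or the preparation of the cells gave them was not tested.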

How the results depend on the processing

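Scaling by library size without normalization factors was chosen after the data were seen; the other alternatives were chosen before. Of 934 results for the genes that the naming rule gave in the 3 main classes, 631 were called, and 462 of these were called in the same direction under every alternative run, leaving out each library included. Over 15609 comparisons of such a result with an alternative, 14703 were counted as the same and kept their side of the threshold, 546 lost the call and 296 gained it. Another 64 stayed uncalled but were counted as moved, with the opposite direction, and 0 called values reversed. Of the 889 comparisons for the 81 lists called in the 3 main classes, 691 kept the call and 198 lost it. The count of called lists in these 3 classes, which leaves out mural and erythroid-like cells, was 81, 80 to 99 when 1 library was left out, and 0 with an estimated correlation, which gave 0 in each of their 9 class comparisons; this alternative widens the test by construction. In the simulations it still found the raised list in 8 of 9, but their genes were drawn independently. They cannot tell how it acts on lists whose genes move together. Where a count below moved otherwise, the cause was not tested, except that leaving out a library or a group leaves fewer residual degrees of freedom; a group left with 1 library was assumed to vary like the others.

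For CLP 24h against CLP 12h in endothelial-like cells (10 genes) DESeq2 called 421, no low-count filter 276, the replicate block 6, only the 2 groups compared 1, classes by marker score 6 and library sizes alone 20. In fibroblast-like cells (526) the replicate block gave 336 and only the 2 groups compared 157. In macrophage or monocyte-like cells (0) DESeq2 gave 45 and no low-count filter 328. In erythroid-like cells (18) it was 41 by DESeq2, 225 with no low-count filter, 28 with the block, 4 with only the 2 groups, 28 with the stricter cell filter, 0 by marker score and 9 with thinned sums. In mural-like cells (4) it was 81, 462, 1 and 0 in the order of the first 4, 8 with doublets kept, 10 by marker score, 10 with thinned sums and 17 with library sizes alone. Against control, DESeq2 gave 1035 and 1524 in erythroid-like cells at CLP 12h and CLP 24h and 2352 in mural-like cells at CLP 12h, thinned sums 1783 in erythroid-like cells at CLP 24h, and marker scores 2425 in mural-like cells at CLP 12h. Over these 2 classes and 3 comparisons together (12961) DESeq2 gave 8282. The class shares (0 called) went to 1 with the stricter cell filter and 4 by DESeq2. By fry 12 lists were called in endothelial-like and 12 in fibroblast-like cells at CLP 24h, 10 in macrophage or monocyte-like cells at CLP 12h, and 0 between the CLP groups in each class. These were in part other lists than those of camera: of the 81 lists that camera called in the 3 main classes, 33 kept the call by fry and 48 lost it. Without genes of other classes 6 lists were called in fibroblast-like cells between the CLP groups.

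Leaving out each of the 6 libraries gave these ranges. In endothelial-like cells they were 3834 to 8378 genes at CLP 12h, 5243 to 8287 at CLP 24h and 0 to 867 between them. In fibroblast-like cells they were 5081 to 8170, 6105 to 7644 and 5 to 1539; in macrophage or monocyte-like cells 1216 to 3545, 1615 to 4111 and 0 to 6; in mural-like cells 919 to 5115, 1962 to 5004 and 0 to 778; in erythroid-like cells 620 to 2384, 1032 to 2690 and 4 to 290, and over the last 2 classes together 4657 to 16150. The lowest counts against control came without a control library in every class named at both times; the sum over the last 2 classes was 4657 without control replicate 1, 4965 without control replicate 2 and 8445 without CLP 12h replicate 1. For lists the ranges were 5 to 11, 5 to 9 and 4 to 11 in endothelial-like, 8 to 9, 6 to 11 and 8 to 14 in fibroblast-like and 15 to 20, 10 to 14 and 7 to 13 in macrophage or monocyte-like cells, and for class shares 0 to 5. The replicate numbers did not pair the libraries: deviations of equal numbers from their group means correlated at -0.149 to 0.104. Changes of 2-fold were recovered least often in simulated data of macrophage or monocyte-like cells: 22.4% at CLP 12h, against 32.8% in endothelial-like and 56.7% in fibroblast-like cells. Fibroblast-like sums held fewer UMIs than endothelial-like sums, so this order did not follow depth alone. The common biological coefficient of variation was highest in macrophage or monocyte-like cells.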

Other observations

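Endocardial-like cells, which line the chambers of the heart, were too few for a test of genes but held the highest Csf3 levels. Csf3 stood at 4460.0 ± 2486 unscaled CPM at CLP 12h and 10650.0 ± 1263 at CLP 24h in this class, without a UMI in control. Lcn2 went from 44.2 ± 9.84 to 21630.0 ± 3253 and 29860.0 ± 2991 unscaled CPM. In lymphatic endothelial-like cells Lcn2 stood at 1884 ± 48.8 unscaled CPM in control and 37120.0 ± 1188 at CLP 24h, and Csf3 at 6960.0 ± 3245 at CLP 24h. These genes were chosen after their values were seen.

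Single clock genes moved, while the whole list was not called. Per1, a clock gene that glucocorticoids also induce, went from 25 ± 2.24 to 137 ± 11.3 and 198 ± 79.3 CPM in endothelial-like cells (log2 fold change 2.45 and 2.99) and rose by 2.43 and 3.0 in fibroblast-like and 2.09 and 2.43 in macrophage or monocyte-like cells. Per2 rose in endothelial-like cells (3.31 and 3.26), while the clock repressor Nr1d1 fell there at CLP 12h (-2.70) and Npas2 fell in fibroblast-like cells at CLP 12h (-3.68). Of the whole circadian clock list, 7 of 14 tested members rose and 3 fell (3 and 3 with library sizes alone, camera adjusted p = 0.184) in endothelial-like cells at CLP 24h. In fibroblast-like cells 4 of 14 tested members rose and 4 fell (camera adjusted p = 0.676) at CLP 24h, and in macrophage or monocyte-like cells 2 of 12 tested members rose and 4 fell (camera adjusted p = 0.509). The hour of day at which the hearts were taken is not given in the sources used here.

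Genes of the unfolded protein response were called in both directions, and camera did not call the list in the comparisons given here. Of that list, 7 of 15 tested members rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.145) in endothelial-like cells at CLP 24h, and 5 rose and 4 fell with library sizes alone. The chaperone Hspa5 went from 551 ± 22.9 to 1353 ± 52.9 CPM (1.30) and the transcription factor Xbp1 from 79.2 ± 7.85 to 423 ± 20.3 CPM (2.42). In fibroblast-like cells 6 of 14 tested members rose and 2 fell (camera adjusted p = 0.185) at CLP 24h, with Hspa5 at 1.31 and Creld2 at -1.19, and 3 rose and 5 fell with library sizes alone.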
